A study of Mus musculus with 12 samples.

How the data were processed

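Bulk RNA sequencing was done on 12 mouse libraries, 3 each of Treg cells from the spleen, Treg cells from the injured spinal cord at day 14 after injury, control primary microglia and primary microglia co-cultured with Treg cells. Messenger RNA was enriched with oligo(dT) beads, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The origin of the Treg cells used in the co-culture is not given in the sources used here.

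The FPKM values were computed by the authors, per the file headers, for 6 libraries per comparison and were deposited with 2 decimals. Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the genome build GRCm38.p6 are named in the submitters' processing notes, without their roles. Each table also held the log2 fold change between group means and a Q value as deposited by the authors, and how the log2 and the Q value were computed is not given in the sources used here. The header of the microglia fold change column named its numerator with a word that no label uses. Its sign matched co-culture over control in every gene, and it was read that way. The authors' deposited tables held only genes with an absolute log2 fold change of at least 1 and a Q value under 0.05, tested on the values, where the smallest absolute log2 fold change was 1.0007 in the Treg cells and 1.0006 in the microglia and the largest Q value was 0.0498 and 0.0497. Such a selection fixes in advance that nearly every gene passes a test, and it makes library totals and adjusted p-values describe the selection alone. In the authors' deposited table the log2 fold change exceeded the log2 ratio of mean FPKM by a median of 0.1189 in the Treg cells (5th to 95th percentile 0.0711 to 0.1666) and 0.2125 in the microglia (0.1677 to 0.2337), so the authors' fold changes are on another scale than the FPKM. Of the Treg genes, 22 had an absolute log2 fold change above 15 in the authors' deposited table, and all 22 were above 0 in 1 library only. Depth is unknown, since the low FPKM values showed no steps that would give read numbers, and no interval for counting error was given. No libraries of a group were copies: the share of genes with equal values above 0 lay between 0.08% and 0.65% for pairs of Treg libraries and between 1.82% and 3.47% for pairs of microglia libraries.

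The tables were normalized separately and were fitted separately. Genes with a mean FPKM of at least 1 over the 6 libraries were kept, which left 1072 of 1284 genes for the Treg cells and 1529 of 2186 genes for the microglia. FPKM values were transformed to log2(FPKM + 1), with a pseudocount of 1, and tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over the genes kept and a threshold of 0.05. The prior degrees of freedom were 7.86 and 2.94. Folds between groups are ratios of mean FPKM, and errors are SDs of FPKM or SEs of the log2 fold change. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for all other steps. Coordinates came from a RefSeq gene table of GRCm38.p6, matched by the NCBI gene IDs of the deposited tables, of which 1282 of 1284 and 2176 of 2186 matched.

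The fit was tested on simulated data drawn around the control means of each comparison, with its within-group spreads. Most simulated genes were unchanged, 872 of 1072 for the Treg cells and 1329 of 1529 for the microglia. The deposited tables hold only genes selected as changed, so the rates of false calls do not carry over to them. For the Treg cells (1072 genes) it recovered 20.9%, 53.7% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold, and 7.5% of its calls were false. For the microglia (1529 genes) it recovered 94.0%, 94.0% and 100.0%, and 4.5% of its calls were false.

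The groups, the tests, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. There were 25 lists per comparison, of pathways, cell states and markers of other cell types. For lists with 5 or more called members, a two-sided Fisher's exact test compared higher against lower calls among members and other called genes, with Benjamini-Hochberg adjustment over those lists. It compares directions within the selected genes and says nothing on enrichment. The competitive test camera of limma was run beside it with a preset correlation of 0.01 and with an estimated one. Genes were named by rule: the 6 largest rises and the 6 largest falls among called genes with a gene symbol, non-overlapping groups and a mean of at least 5 FPKM in the higher group, and the 2 members with the largest absolute log2 fold change of each list with 3 or more called members (up to 4 for the sterol, LXR and Treg identity lists). Foxp3 and Il2ra for the Treg cells, and Foxp3, Cd3e, Abca1, Apoe, Hmgcs1 and Srebf2 for the microglia, were also on the rule and are not analysed here. The rule gave 35 genes for the Treg cells and 38 for the microglia, and some results for single genes and 1 gene family are not reported here. Other genes named with a list, and all gene families in the closing section, were chosen after their values were seen.

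The alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, equal totals over the table, quantile normalization, no mean-variance trend, the replicate number as a block, the camera tests, and each library left out in turn. A shift of the FPKM to the scale of the authors' fold changes, and equal totals for the list tests, were added after the data were seen. Count models were not used, since the values are not counts.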

Results

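Messenger RNA was sequenced in bulk from 12 mouse libraries, which fell into 4 groups of 3. Regulatory T (Treg) cells, the T cells that restrain immune responses, were isolated 14 days after spinal cord injury from the injured cord (n = 3) and from the spleen (n = 3). Primary microglia, the resident macrophages of the central nervous system kept in culture, were left unstimulated as the control (n = 3) or were cultured together with Treg cells (n = 3). The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. Expression was given as FPKM, a fragment count scaled by transcript length and library total, in one table per comparison. Each table held only genes that the authors had found changed, 1284 genes for the Treg cells and 2186 genes for the microglia. The genes were thus chosen on these same libraries, so the counts of changed genes and their directions are not independent evidence, and a gene without a row is not analysed here. Sequencing depth is unknown. The FPKM summed over the table lay between 64893 and 65362 in the spleen libraries and between 111243 and 134887 in the spinal cord libraries. It lay between 59529 and 61068 in the control microglia and between 115884 and 117408 in the co-cultured microglia. These are sums over selected genes, not library sizes.

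The first comparison asked how Treg cells of the injured spinal cord differed from those of the spleen at the same time, in a study of how these cells protect the injured cord. All 11 tested genes of the type I interferon list rose in the spinal cord (two-sided Fisher's exact test of direction against the other called genes, adjusted p = 0.0265). In camera, limma's competitive set test, the adjusted p was 0.00506 with the preset correlation and 0.292 with an estimated correlation. All 7 tested genes of the list of activated and tissue Treg cells and all 7 of the list of resting lymphoid T cells rose with the values as deposited, and neither list passed the exact test (adjusted p = 0.0712 for both). Among single genes, Ifitm3 rose by a log2 fold change of 6.16 (SE 0.39) and Ccl1 changed by -5.0 (SE 0.71), with 3 libraries on each side. The value of Ccl1 was -3.82 without spinal cord library 1, where it was listed at 0, and -5.72 without spinal cord library 3. Of 1072 genes tested with limma, 654 were higher and 414 lower in the spinal cord at a Benjamini-Hochberg adjusted p under 0.05, and 4 did not pass. The log2 fold change reached at least 2 in 135 of the higher and 19 of the lower genes. All fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Scaling every library to the same total over the table moved the log2 fold changes of single genes by a median of -0.85, and their median went from 0.95 to 0.09. It left 680 genes called, 266 higher and 414 lower, 39.1% higher against 61.2% with the values as deposited. Quantile normalization moved single genes by a median of -0.39 and brought the median log2 fold change to 0.52. Both scalings use genes selected for a change, so part of a shared shift is removed by construction. A shift to the scale of the authors' fold changes moved single genes by a median of 0.11, with 655 called higher and 413 lower.

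The largest rises were in Ifitm3, Plac8, Ifi27l2a, Slpi, Usp18 and Plaur. Ifitm3 (NCBI gene 66141, chromosome 7, 141009590 to 141010744, GRCm38.p6), an interferon-induced membrane protein that restricts virus entry, rose from 1.61 ± 1.57 FPKM in the spleen to 161 ± 9.59 FPKM in the spinal cord (SD, n = 3 each). Its log2 fold change was 6.16 (SE 0.39, limma with Benjamini-Hochberg adjusted p = 2.21e-07). Ifi27l2a (gene 76933, chromosome 12, 103433873 to 103443680), another interferon-inducible gene, rose 44.2-fold, from 37.1 ± 8.40 to 1640 ± 356 FPKM. Plaur (gene 18793, chromosome 7, 24460937 to 24475970), the urokinase receptor, rose 35.0-fold to 281 ± 22.6 FPKM. Usp18 (gene 24110, chromosome 6, 121245906 to 121270917), the protease that removes ISG15 from proteins and damps type I interferon signalling, stood at 3.60, 2.63 and 0.22 FPKM in the spleen libraries and at 112, 53.3 and 112 FPKM in the spinal cord libraries. Plac8 (gene 231507, chromosome 5, 100551589 to 100572253) was listed at 0 in 2 spleen libraries and at 1.79 FPKM in the other, against 74.3, 68.4 and 79.1 FPKM in the spinal cord. Slpi (gene 20568, chromosome 2, 164354070 to 164356507), a secreted peptidase inhibitor, was likewise listed at 0 in 2 spleen libraries and reached 72.6, 61.5 and 42.6 FPKM in the spinal cord.

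The largest falls were in Ccl1, Cyp1a1, Ccl3, Il1a, Rxra and Bag2. The chemokine gene Ccl1 (gene 20290, chromosome 11, 82176666 to 82179812) held 158, 168 and 164 FPKM in the spleen and 0, 8.67 and 12.9 FPKM in the spinal cord, a log2 fold change of -5.0 (SE 0.71, limma adjusted p = 6.51e-05). This size rested in part on the library at 0, since it was -3.82 without spinal cord library 1 and -5.72 without library 3, and the limma call held in both. Ccl3 (gene 20302, chromosome 11, 83647843 to 83649378), a second chemokine gene, fell from 343 ± 30.4 to 50.6 ± 19.9 FPKM. Il1a (gene 16175, chromosome 2, 129299609 to 129310186), which encodes interleukin 1 alpha, was 7.29-fold lower in the spinal cord. Cyp1a1 (gene 13076, chromosome 9, 57687928 to 57703824), a target of the aryl hydrocarbon receptor, fell from 43.2 ± 5.68 to 5.00 ± 2.61 FPKM. Rxra (gene 20181, chromosome 2, 27676445 to 27763319), a partner of many nuclear receptors, was 9.20-fold lower, and the cochaperone gene Bag2 (gene 213539, chromosome 1, 33745484 to 33757750) was 8.58-fold lower.

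**Figure D1:**
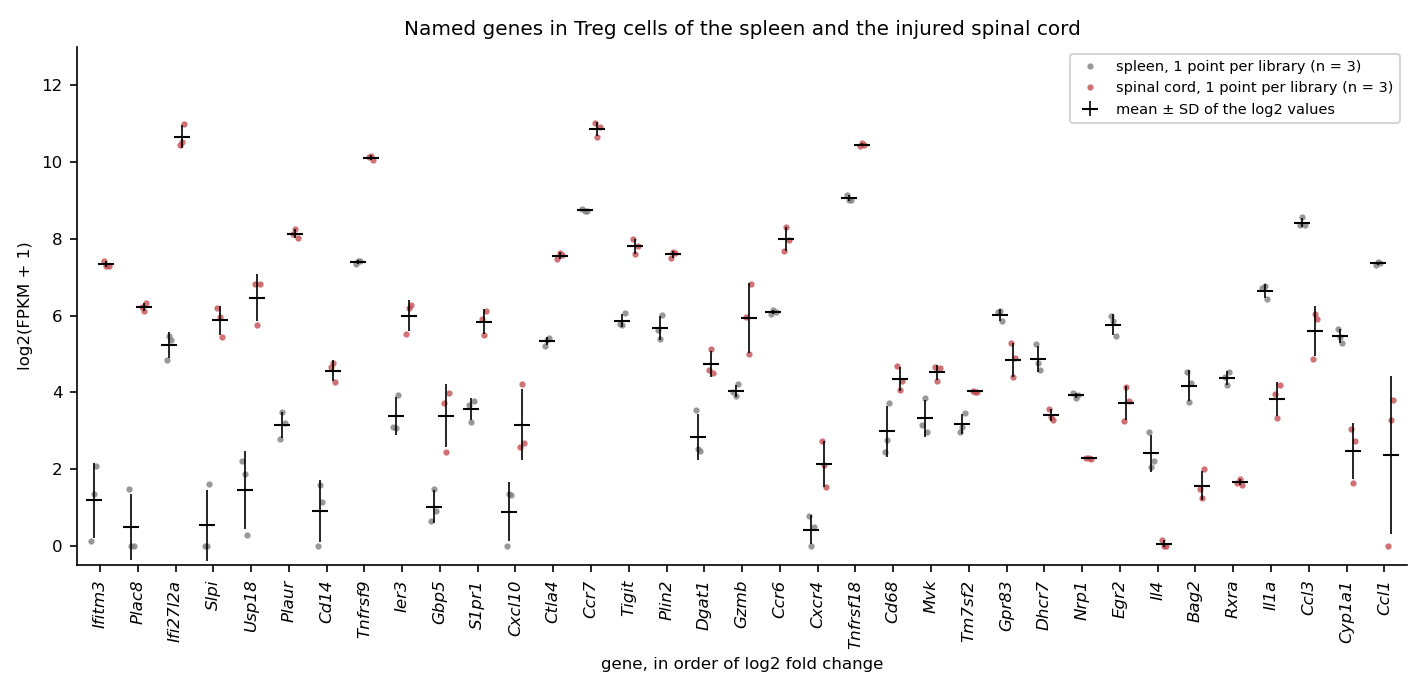
Expression of 35 named genes in Treg cells, as log2(FPKM + 1) on the vertical axis, with genes on the horizontal axis in order of log2 fold change; each point is 1 library (n = 3 per tissue) and the bars give the mean ± SD of the log2 values. The log2 fold changes ran from 6.16 in Ifitm3 to -5.0 in Ccl1, which was -3.82 without spinal cord library 1 and -5.72 without library 3.

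Of the Treg cell identity list, 4 of 14 genes were tested, and 2 were higher and 2 lower. Ctla4, an inhibitory receptor of Treg cells, rose 4.78-fold to 188 ± 11.5 FPKM, with a log2 fold change of 2.23 (SE 0.15). Tnfrsf18, the receptor GITR, rose from 533 ± 30.2 to 1400 ± 38.3 FPKM, a call that quantile normalization ended (log2 fold change 0.10, limma adjusted p = 0.435). Nrp1, a semaphorin coreceptor, fell from 14.1 ± 0.644 to 3.86 ± 0.0493 FPKM, and Gpr83, an orphan receptor, was 2.23-fold lower. Foxp3 and Il2ra are not analysed here.

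All 7 tested members of the list of activated and non-lymphoid tissue Treg cells (23 genes) rose, of which 5 were called with equal totals. Tnfrsf9, the costimulatory receptor 4-1BB, rose 6.63-fold to 1110 ± 48.8 FPKM, and the inhibitory receptor gene Tigit rose 3.90-fold. Lag3, Icos, Tnfrsf4, Rora and Bhlhe40 were the others. All 7 tested members of the list of resting lymphoid T cells (13 genes) rose with the values as deposited, while with equal totals 5 were called and Actn1 lay below 0. Ccr7, the chemokine receptor for lymph node homing, rose from 428 ± 5.92 to 1860 ± 236 FPKM, and S1pr1, the receptor for exit from lymphoid tissue, rose from 10.9 ± 2.23 to 57.4 ± 12.5 FPKM. Il7r, Satb1 and Dapl1 rose as well. Neither list passed the test of direction on the values as deposited (two-sided Fisher's exact test, adjusted p = 0.0712 for both), while the exact test gave adjusted p = 0.00895 for both with equal totals. In limma's camera the adjusted p was 0.00911 and 0.0331 with the preset correlation and 0.292 and 0.316 with an estimated correlation.

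All 11 tested members of the type I interferon list rose, of which 10 were called with equal totals and after quantile normalization, and their direction differed from that of the other called genes (Fisher's exact test, adjusted p = 0.0265). In limma's camera that call held with the preset correlation (adjusted p = 0.00506) and was lost with an estimated one (adjusted p = 0.292). Isg15, a ubiquitin-like modifier, went from 2.11, 0.07 and 0.07 FPKM to 33.9, 28.9 and 34.6 FPKM, and Irf7, a transcription factor of the interferon response, had a log2 fold change of 3.85. All 10 tested members of the list of interferon gamma response and antigen presentation were higher with the values as deposited (adjusted p = 0.0265, exact test), while with equal totals 4 were called and 2 lay below 0, and 3 lay below 0 after quantile normalization. The exact test gave adjusted p = 0.0513 after quantile normalization, and the camera adjusted p was 0.0259 with the preset correlation and 0.316 with an estimated correlation. Gbp5, a guanylate-binding protein of cell-autonomous defence, rose from 0.57, 1.81 and 0.87 FPKM in the spleen libraries to 12.3, 4.48 and 14.8 FPKM in the spinal cord libraries. The chemokine gene Cxcl10 was listed at 0, 1.54 and 1.48 FPKM in the spleen and at 4.93, 17.6 and 5.34 FPKM in the spinal cord. Guanylate-binding proteins, class I H2 genes and interferon-induced membrane proteins have close paralogs, and how the authors shared reads among such copies is not given in the sources used here.

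Among suppressive and cytolytic effectors, 4 of 5 tested genes rose and 1 fell with the values as deposited (Fisher's exact test, adjusted p = 0.785), while with equal totals 1 was called higher and 1 lower. Gzmb, which encodes granzyme B, rose 4.40-fold, and Il10, Ebi3 and Il17a rose with log2 fold changes of 1.17, 1.26 and 1.33, calls that ended with equal totals. Il4 fell from 6.79, 3.16 and 3.65 FPKM to 0.11, 0 and 0 FPKM. All 4 tested genes for chemokine receptors rose with the values as deposited, and 2 of them were called with equal totals. Ccr6 rose 3.81-fold to 256 ± 56.1 FPKM, and Cxcr4 stood at 0.70, 0 and 0.41 FPKM in the spleen and 5.61, 3.31 and 1.88 FPKM in the spinal cord. Of 6 tested early response and heat shock genes, 4 rose and 2 fell (adjusted p = 1, exact test), while with equal totals 3 lay below 0, and 1 was called higher and 2 lower. Ier3 rose 6.62-fold and Egr2 fell 4.29-fold to 12.6 ± 4.08 FPKM.

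Of the sterol synthesis list, 3 of 25 genes were tested. Dhcr7, an enzyme of the last steps of cholesterol synthesis, fell from 28.7 ± 7.32 to 9.62 ± 1.12 FPKM. Mvk, mevalonate kinase, rose 2.37-fold and Tm7sf2, a sterol reductase, 1.88-fold, but with equal totals neither was called (limma adjusted p = 0.377 and 0.994) and Tm7sf2 lay at -0.01. Among LXR targets, Npc2 rose and Fasn fell. All 3 tested genes of lipid uptake and storage rose, of which 2 were called with equal totals, among them Plin2, a coat protein of lipid droplets, which went from 50.7 ± 11.5 to 193 ± 11.9 FPKM, and Dgat1, a triglyceride synthase, which rose 3.97-fold. Slc16a3 and Ndrg1 of the glycolysis and hypoxia list rose, and so did Ndufa1 of the oxidative phosphorylation list, which lay below 0 with equal totals.

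Markers of other cells moved with the tissue. All 4 tested microglia and macrophage markers rose with the values as deposited, while with equal totals 1 was called and 1 lay below 0. Cd14, a lipopolysaccharide coreceptor of myeloid cells, was at 0, 2.00 and 1.20 FPKM in the spleen and 24.5, 26.2 and 18.1 FPKM in the spinal cord, and Cd68, a lysosomal glycoprotein of macrophages, rose 2.62-fold. The call of Cd68 ended with equal totals (limma adjusted p = 0.243). The neutrophil markers S100a8 and Mmp8, the endothelial markers Pecam1 and Ly6c1, and Cnp of the oligodendrocyte list rose, Cd79b of the B cell list was listed at 0 in every spleen library and stood at 5.38, 3.13 and 2.66 FPKM in the spinal cord, while Nefh of the neuron list fell. Of the list of CD8 T, NK and gamma-delta T cells, Klrk1 rose and Xcl1 fell. The fibroblast list had 1 gene with a row, which was below the filter. Growth and repair factors, cell cycle genes, and astrocyte and erythroid markers are not analysed here for the Treg cells.

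The second comparison asked what changed in microglia cultured with Treg cells. All 21 tested genes of the interferon gamma list, all 16 pro-inflammatory mediators and all 11 genes of alternative activation rose with the values as deposited. Of the 20 genes on the homeostatic microglial list 8 were tested, and 7 of these fell. These lists passed the two-sided Fisher's exact test of direction (adjusted p = 2.15e-05, 1.83e-04, 0.00239 and 0.0432). In limma's camera they passed with the preset correlation (adjusted p = 4.32e-05, 0.00219, 0.00219 and 0.00846) and did not pass with an estimated correlation (adjusted p = 0.182, 0.20, 0.347 and 0.182). Among single genes, Arg1 rose by a log2 fold change of 6.89 (SE 0.35) and Cx3cr1 changed by -5.80 (SE 0.09), with 3 libraries on each side. Of 1529 genes tested with limma, 817 were higher and 712 lower in co-culture at a Benjamini-Hochberg adjusted p under 0.05, and none failed to pass. The log2 fold change reached at least 2 in 194 of the higher and 80 of the lower genes. Equal totals over the table moved the log2 fold changes of single genes by a median of -0.83, and their median went from 0.74 to -0.11. With equal totals 537 genes were called higher and 731 lower, 42.4% higher against 53.4% with the values as deposited. Quantile normalization moved single genes by a median of -0.26 and brought the median log2 fold change to 0.02.

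The largest rises were in Arg1, Gbp2, Ccl24, Iigp1, Gbp4 and Serpina3g. Arg1 (gene 11846, chromosome 10, 24915207 to 24927470), the arginase of alternatively activated macrophages, rose 117-fold from 12.7 ± 6.72 to 1480 ± 37.5 FPKM (SD, n = 3 each). Its log2 fold change was 6.89 (SE 0.35, limma with Benjamini-Hochberg adjusted p = 6.66e-07). Gbp2 (gene 14469, chromosome 3, 142620663 to 142638008), an interferon-induced GTPase, rose from 17.8 ± 8.39 to 2060 ± 43.1 FPKM. Ccl24 (gene 56221, chromosome 5, 135569935 to 135573123), a chemokine for eosinophils, rose to 847 ± 68.0 FPKM, and Iigp1 (gene 60440, chromosome 18, 60373616 to 60392634), another GTPase, to 594 ± 9.76 FPKM. Gbp4 (gene 17472, chromosome 5, 105115767 to 105139586) rose 131-fold and Serpina3g (gene 20715, chromosome 12, 104236147 to 104241939) 126-fold. The control libraries differed among themselves in these genes. Arg1 stood at 19.3, 5.90 and 12.8 FPKM and Ccl24 at 10.7, 2.95 and 7.13 FPKM in controls 1, 2 and 3. Serpina3g and the guanylate-binding proteins have close paralogs.

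The largest falls were in Cx3cr1, Cxcr4, Hpgd, Dkk2, Acta2 and Stap1. Cx3cr1 (gene 13051, chromosome 9, 120048683 to 120068296), the fractalkine receptor of microglia, fell from 136 ± 8.86 to 1.45 ± 0.253 FPKM, a log2 fold change of -5.80 (SE 0.09, limma adjusted p = 9.26e-09). The chemokine receptor gene Cxcr4 (gene 12767, chromosome 1, 128588199 to 128592299) fell 36.4-fold. Hpgd (gene 15446, chromosome 8, 56294552 to 56321046), which inactivates prostaglandins, was 36.2-fold lower, and Dkk2 (gene 56811, chromosome 3, 132085266 to 132180304), a secreted modulator of Wnt signalling, 28.5-fold lower. Acta2 (gene 11475, chromosome 19, 34240336 to 34255585), smooth muscle actin, fell from 318 ± 34.3 to 24.0 ± 7.80 FPKM. The adaptor gene Stap1 (gene 56792, chromosome 5, 86071584 to 86106125) was 17.3-fold lower.

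**Figure D2:**
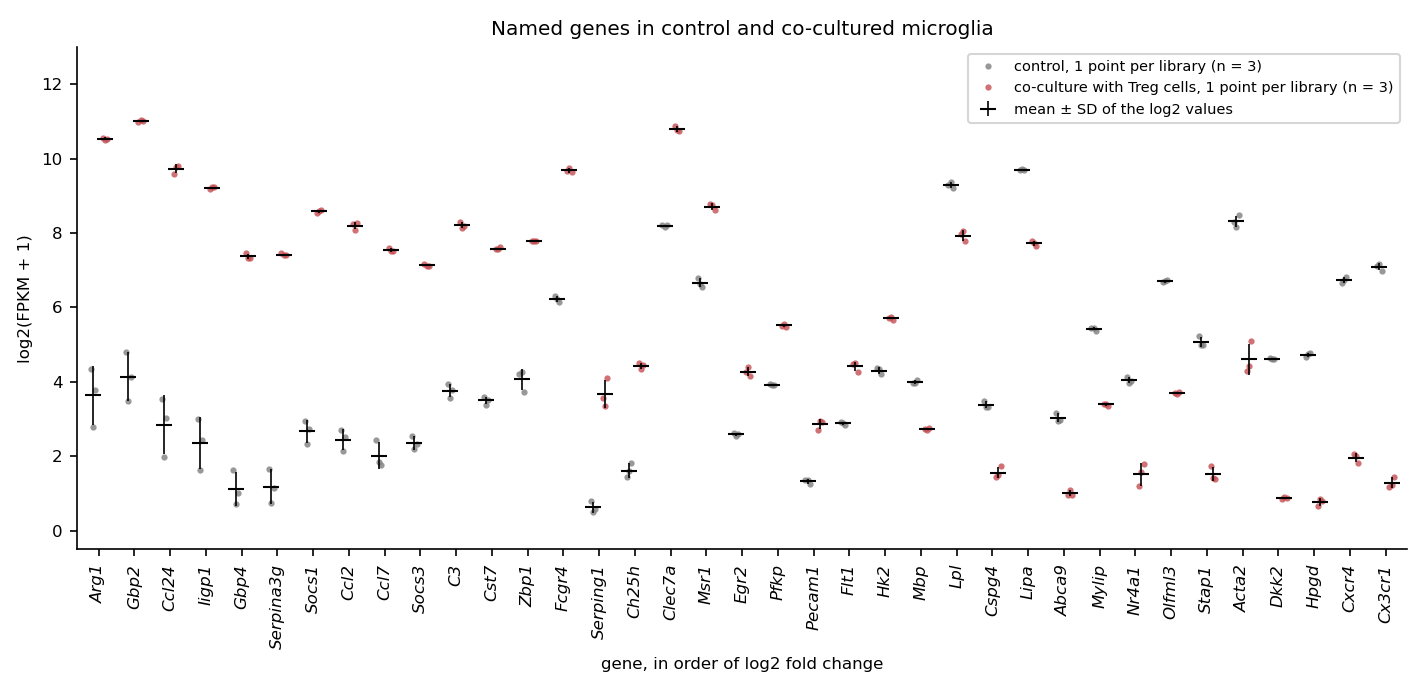
Expression of named genes in microglia, as log2(FPKM + 1) on the vertical axis, with genes on the horizontal axis in order of log2 fold change; each point is 1 library (n = 3 per group) and the bars give the mean ± SD of the log2 values. The log2 fold changes ran from 6.89 in Arg1 to -5.80 in Cx3cr1.

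All 21 tested members of the list of interferon gamma response and antigen presentation rose with the values as deposited, and 1 lay below 0 after quantile normalization. Their direction differed from that of the other called genes (two-sided Fisher's exact test, adjusted p = 2.15e-05). The camera adjusted p with an estimated correlation was 0.182. The class II genes H2-Aa, H2-Ab1 and H2-Eb1, their chaperone Cd74 and their transactivator Ciita had log2 fold changes of 4.88, 4.98, 4.19, 5.51 and 2.53. Cxcl9, a chemokine for activated T cells, went from 1.69, 0.53 and 1.14 FPKM to 147, 145 and 151 FPKM. All 17 tested members of the type I interferon list rose (adjusted p = 1.43e-04, exact test), although with equal totals 14 were called and 1 lay below 0. The camera adjusted p with an estimated correlation was 0.565. Zbp1, a sensor of Z-form nucleic acids, rose 13.7-fold to 219 ± 1.05 FPKM. Control 3 was below controls 1 and 2 in this gene, with 12.3 FPKM against 17.4 and 18.3 FPKM.

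All 16 tested pro-inflammatory mediators rose, of which 14 were called with equal totals (Fisher's exact test on the deposited values, adjusted p = 1.83e-04), and the camera adjusted p with an estimated correlation was 0.20. The monocyte chemokine genes Ccl2 and Ccl7 rose 65.0-fold and 59.0-fold, to 294 ± 20.9 and 186 ± 7.42 FPKM. Nos2, the inducible nitric oxide synthase, had a log2 fold change of 4.81, and Tnf and Il1b of 1.76 and 2.26. All 11 tested genes of alternative activation rose too (adjusted p = 0.00239, exact test), with a camera adjusted p of 0.347 with an estimated correlation. Besides Arg1 and Ccl24 they included Mrc1, the mannose receptor, with a log2 fold change of 2.73, and Il1rn, the interleukin 1 receptor antagonist, with 3.14.

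All 11 tested genes of interleukin 2, 4 and 10 family signalling rose (Fisher's exact test, adjusted p = 0.00239). The camera adjusted p with an estimated correlation was 0.347. Socs1 and Socs3, inhibitors of cytokine signalling that also stand in the alternative activation list, rose 69.9-fold to 383 ± 8.40 FPKM and 33.4-fold to 139 ± 2.65 FPKM. Il4ra, a subunit of the interleukin 4 receptor that also stands in the alternative activation list, had a log2 fold change of 3.22 and Il21r of 2.92. Of 12 tested complement and phagocytic receptor genes, 11 rose and 1 fell (adjusted p = 0.0129, exact test), and with equal totals 9 were called higher and 1 lower, while 2 lay below 0 after quantile normalization. The camera adjusted p with an estimated correlation was 0.182. The complement gene C3 rose 23.3-fold to 295 ± 16.8 FPKM and Fcgr4, an activating Fc receptor, rose 11.0-fold to 821 ± 32.4 FPKM. Gas6, a ligand of phagocytic receptors, fell with a log2 fold change of -2.06.

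Of 8 tested homeostatic microglial genes (20 on the list), 7 fell and 1, Gpr84, rose with the values as deposited and lay below 0 with equal totals (Fisher's exact test on the deposited values, adjusted p = 0.0432). The camera adjusted p with an estimated correlation was 0.182, and the exact test gave 0.129 without a filter on low genes and 0.0619 after quantile normalization. Olfml3, a secreted protein of microglia, fell 8.64-fold from 103 ± 2.37 FPKM, and Gpr34, Tmem119, Tgfbr1, Mef2c and Sparc fell with it. Sparc is also expressed by fibroblasts, and it was highest in co-culture 3 among the co-cultures, at 63.1 FPKM against 36.4 and 36.7. Of 8 tested genes of disease-associated microglia (21 on the list), 4 rose and 4 fell (adjusted p = 1, exact test). Cst7, a cathepsin inhibitor, rose 18.5-fold and Clec7a, the beta-glucan receptor dectin 1, rose 6.14-fold to 1790 ± 91.4 FPKM, while Igf1, Csf1, Ank and Lpl fell.

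Cholesterol genes went both ways. Of 8 tested LXR targets and efflux genes, 4 rose and 4 fell with the values as deposited (Fisher's exact test, adjusted p = 1), while 6 lay below 0 with equal totals and 5 after quantile normalization, of which 5 were called lower under each scaling. Ch25h, which makes 25-hydroxycholesterol, rose 9.94-fold from 2.08 ± 0.413 to 20.7 ± 1.18 FPKM, and Abcg1, a cholesterol exporter, rose with a log2 fold change of 1.11. Lipa, the lysosomal lipase that releases cholesterol from its esters, fell 3.93-fold from 826 ± 9.11 to 210 ± 9.67 FPKM. Mylip, the ligase that degrades the LDL receptor, fell 4.42-fold and Abca9, a lipid transporter gene, 7.09-fold. Nr1h3, which encodes LXR alpha, and Npc2, a lysosomal cholesterol carrier, rose with log2 fold changes of 0.62 and 0.82 with the values as deposited, while Nr1h3 lay below 0 with equal totals and Npc2 with equal totals and after quantile normalization. The sterol synthesis list, with Hmgcs1 and Srebf2, and also Abca1 and Apoe, are not analysed here. Of 4 tested genes of lipid uptake and storage, 2 rose and 2 fell. Msr1, a scavenger receptor, rose 4.17-fold, and Lpl, lipoprotein lipase, fell 2.58-fold from 630 ± 35.9 to 244 ± 22.9 FPKM.

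All 11 tested genes of glycolysis and hypoxia rose with the values as deposited (Fisher's exact test, adjusted p = 0.00239), while with equal totals 4 lay below 0, of which 1 was called lower, and after quantile normalization 3 lay below 0, of which 2 were called lower. The exact test then gave adjusted p = 0.0695 and 0.145, and the camera adjusted p with an estimated correlation was 0.246. Pfkp, phosphofructokinase, rose 3.16-fold and Hk2, a hexokinase, 2.74-fold to 51.5 ± 1.19 FPKM. Of 5 tested early response genes, 3 rose and 2 fell (adjusted p = 1, exact test), and 3 were called lower with equal totals and after quantile normalization. Egr2 rose 3.65-fold and Nr4a1 fell 8.17-fold. Ccnb2 of the cell cycle list fell, and Ctss of the lysosome list and Cox5a of the oxidative phosphorylation list rose.

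Markers of other cells moved with co-culture. Of 10 tested fibroblast and mural cell genes, 8 fell and 2 rose (Fisher's exact test, adjusted p = 0.0694). Col1a1 fell with a log2 fold change of -2.15, while Serping1, a complement inhibitor, rose from 0.553 ± 0.167 to 12.1 ± 3.62 FPKM and Dcn rose with 1.77. All 10 were highest in co-culture 3 among the co-cultures, at a median of 1.85 times the mean of co-cultures 1 and 2. All 3 tested endothelial markers rose, of which 2 were called with equal totals, among them Pecam1, 4.19-fold to 6.30 ± 0.681 FPKM, and Flt1, 3.19-fold. Of 4 tested genes of the oligodendrocyte lineage, Mag and Cnp rose with the values as deposited, while Cnp lay below 0 with equal totals, and Cspg4 and Mbp fell 4.82-fold and 2.65-fold. Of the T cell list, 6 genes had a row, and the 2 genes tested, Cd28 and Thy1, fell, with log2 fold changes of -2.38 and -1.45. The others with a row were below the filter, and their directions are not given here. The 2 tested genes thus do not show whether RNA of Treg cells was present in the co-cultures. Thy1 stood at 31.6, 22.5 and 44.0 FPKM in the controls and at 10.1, 7.50 and 17.0 FPKM in the co-cultures. It was thus present in cultures without added Treg cells, and it was highest in co-culture 3, as were the 10 fibroblast and mural cell genes. Aqp4 of the astrocyte list fell and Lcn2 of the neutrophil list rose. Both neuron genes with a row were below the filter. Foxp3, Cd3e, and B cell and erythroid markers are not analysed here for the microglia.

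For each list of both comparisons, the count of members called was the same when p-values were adjusted over the list alone. Of the lists with 5 or more called members, 2 of 6 in the Treg cells and 8 of 12 in the microglia passed the exact test, and none of these calls held in limma's camera with an estimated correlation. With the preset correlation all of them held, at a camera adjusted p of 0.00506 and 0.0259 in the Treg cells and between 4.32e-05 and 0.00846 in the microglia. At an unadjusted p under 0.05, camera with an estimated correlation called 0 lists in the Treg cells and 3 in the microglia, and with a preset correlation of 0.01 it called 4 and 8.

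**Figure D3:**
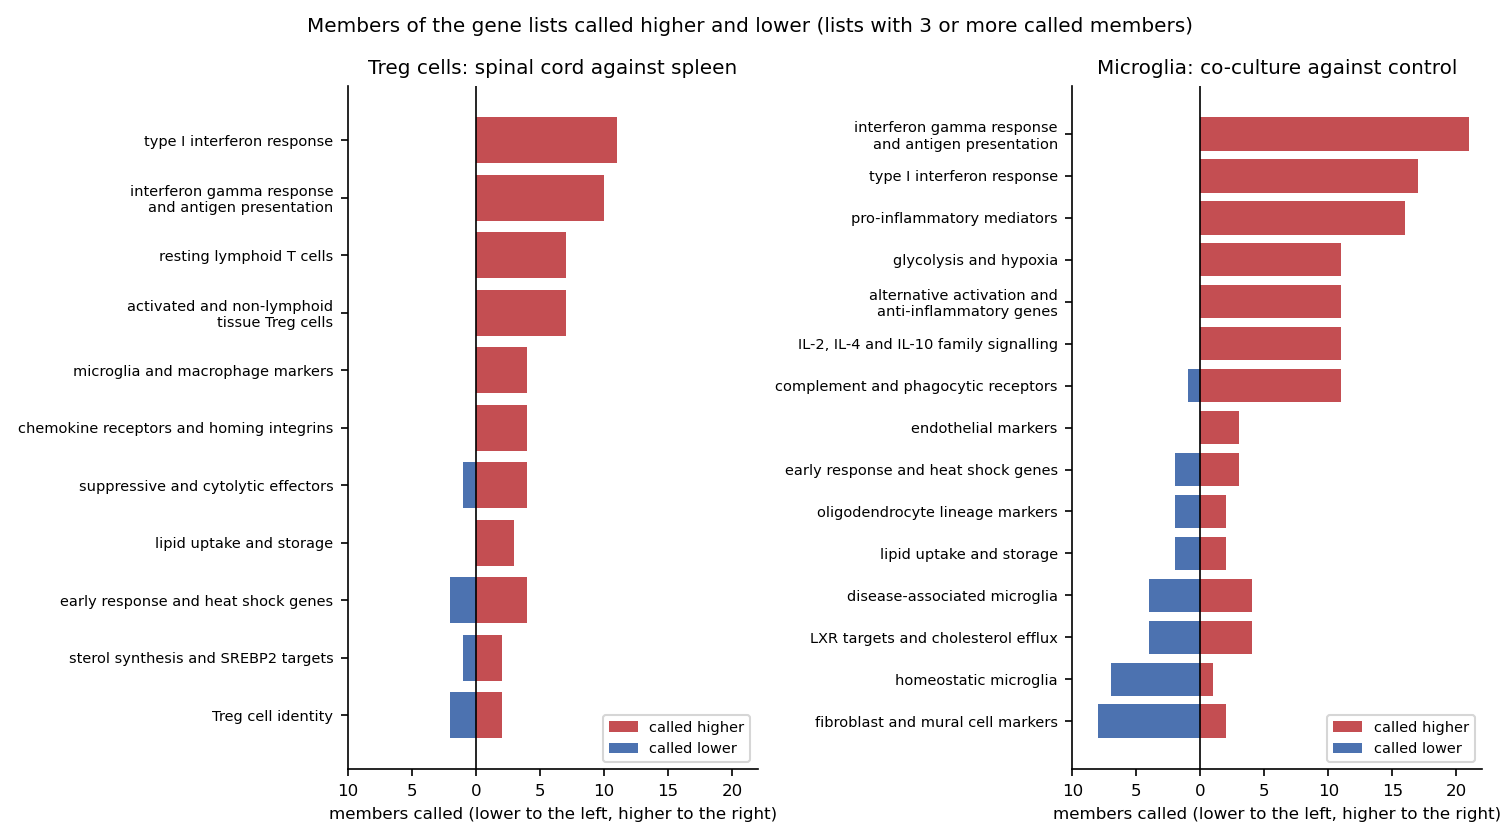
Number of members called higher (bars to the right of 0) and called lower (bars to the left) on the horizontal axis for each gene list with 3 or more called members, in Treg cells (left) and microglia (right). In microglia all 21 called genes of the interferon gamma response were higher with the values as deposited, of which 1 lay below 0 after quantile normalization. Of 20 genes on the homeostatic list 8 were called, and 7 of these were lower.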

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

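The shift to the authors' scale, and equal totals for the lists, were tests chosen after the results were seen. Among the named genes, no microglial gene changed its call or direction under any alternative in which it was tested. These genes were picked for large changes among genes already selected for a change, so stable calls were likely in advance. The filter at 5 FPKM kept 36 of the 38 microglial genes. In the Treg cells 484 of the values under alternatives kept both call and direction, 3 lost the call and 1 reversed. The reversed value was that of Tm7sf2 with equal totals (log2 fold change -0.01, against 0.85), and the lost calls were those of Tnfrsf18 after quantile normalization (0.10) and of Mvk (0.34) and Cd68 (0.52) with equal totals. Equal totals called 680 genes in the Treg cells, all among the 1068, with 266 higher, and in the microglia left 537 higher. These scalings subtract a shift of most genes by construction, so a call lost under them may be due to the scaling alone. The shift to the authors' scale moved single genes by a median of 0.11 in the Treg cells and 0.19 in the microglia. It called 655 genes higher and 413 lower in the Treg cells, and 817 higher and 712 lower in the microglia. Quantile normalization called 906 and 1424 genes. A filter at 5 FPKM tested fewer genes and called 1001 of 1001 in the microglia, 341 of them lower, and no filter tested more and called 1150 lower. In the Treg cells, the lists past the threshold numbered 2, against 1 after quantile normalization, 3 with equal totals (type I interferon and the tissue Treg and resting lymphoid lists, while the interferon gamma list kept 4 called members, too few for a test), 4 in camera with the preset correlation and 0 with an estimated correlation. In the microglia they numbered 8, against 6 after quantile normalization, 7 with equal totals, 7 without a filter, 8 in camera with the preset correlation and 0 with an estimated correlation. In the homeostatic and complement lists of the microglia the estimated correlation was -0.112 and -0.045, below the preset 0.01. The loss of these 2 calls in camera with an estimated correlation was thus not due to correlation between their genes. Why the other calls of lists differed between tests was not examined and the cause was not tested.

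Adjusted p-values over the alternatives, limma's camera included, ranged from 2.27e-04 to 0.292 for the type I interferon list of the Treg cells, from 0.0226 to 0.316 for the interferon gamma list, and from 0.00895 to 0.292 and to 0.316 for the tissue Treg and resting lymphoid lists. In the microglia the range was 0.00846 to 0.182 for the homeostatic list and 6.77e-04 to 0.246 for glycolysis.

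Leaving out each library in turn gave between 1032 and 1043 called genes in the Treg cells (620 to 631 higher, 408 to 412 lower) and 2 lists each time, and between 1528 and 1529 genes in the microglia (816 to 817 higher, 712 lower) and 8 lists each time. With the replicate block, 1064 genes (650 higher, 414 lower) and 2 lists were called in the Treg cells, and 1529 genes (817 higher, 712 lower) and 8 lists in the microglia. The genes were selected for a difference on all 6 libraries, the one left out included. These counts were thus bound to stay near those of the full fit and are no evidence of robustness. Libraries with the same number had correlations of their deviations of -0.003, -0.041 and -0.053 in the Treg cells and -0.041, 0.149 and 0.175 in the microglia, and not every library correlated best with its own number, so the numbers were not taken to pair them.

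Of the 10 splits of the 6 Treg libraries, 1, the real one, called 1068 genes in limma, and the highest other called 0 at an adjusted and 21 at an unadjusted p under 0.05. Of the 10 splits of the microglia libraries, 1, the real one, called 1529, and the highest other called 0 and 1. With 10 splits no share under 0.05 can be reached. The genes were also selected for a difference under the real grouping. Other splits were thus bound to call few of them, and these counts are no evidence for the grouping. Depth is unknown, so what it limits could not be computed.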

Other observations

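All gene families and tests in this part were chosen after the results were seen, so the p-values of families describe how their directions differed from those of the other called genes and are no evidence for a pattern the families were picked for. In spinal cord Treg cells, all 37 called genes of ribosome assembly, with Nop2, Rrp12, Heatr1, Ncl, Npm1 and the RNA polymerase I subunits Polr1a and Polr1b, were lower, by log2 fold changes between -1.83 and -1.04 and also under each scaling tried (two-sided Fisher's exact test against the other called genes, adjusted p = 2.75e-15 over 13 tests). The 10 called genes of cytosolic ribosomal proteins were higher with the values as deposited (adjusted p = 0.0125, exact test), but with equal totals 0 were called in limma and 4 lay below 0 (median log2 fold change 0.02), and after quantile normalization 1 was called and 6 lay below 0 (median -0.14). All 4 called GIMAP genes, GTPases of lymphocyte survival, were higher, with a median log2 fold change of 1.64, which was 0.71 with equal totals, where 3 were called, and 0.91 after quantile normalization. The guanylate-binding proteins and immunity-related GTPases were higher in all 10 called members in the Treg cells (median 1.39, adjusted p = 0.0125, exact test), of which 3 were called with equal totals, and in all 16 in the microglia (median 5.32, adjusted p = 1.98e-04).

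In co-cultured microglia 16 of 17 chemokine genes rose (median log2 fold change 3.50, Fisher's exact test, adjusted p = 0.00128), against 3 higher and 2 lower in the Treg cells (adjusted p = 1), and all 10 called class I genes rose (adjusted p = 0.00501, exact test). All 7 proteasome genes rose with the values as deposited (adjusted p = 0.022, exact test), among them the immunoproteasome subunits Psmb8, Psmb9 and Psmb10, while 1 lay below 0 with equal totals. Many of the chemokine genes, such as Ccl2, Cxcl9 and Ccl24, also stand in lists reported above. So do H2-K1, Psmb8, Psmb9, and Gbp2, Gbp3, Gbp4 and Gbp5 of the GTPases, so these families in part repeat those lists. All 15 called collagen genes fell (adjusted p = 6.30e-05, exact test), and 11 of 12 genes of the contractile cytoskeleton fell (adjusted p = 0.00501, exact test). Of these, 4 collagen genes and 1 contractile gene also stand in the fibroblast and mural cell list, in which 8 of 10 genes fell. All 15 collagen genes and 11 of the 12 contractile genes were highest in co-culture 3 among the co-cultures, at a median of 1.76 and 1.65 times the mean of co-cultures 1 and 2. All 5 called genes for glutathione S-transferases fell in the microglia (median -2.37, adjusted p = 0.0257, exact test), while all 4 called in the Treg cells were higher (median 1.35), of which 1 was called with equal totals. In both comparisons 204 genes were called, of which 142 were higher in both, 13 lower in both, 39 higher in the spinal cord and lower in co-culture, and 10 the reverse. The same direction was shared by 76.0%, against 69.0% from the margins (odds ratio 4.73, Fisher's exact p = 7.42e-04). Genes are not independent replicates, and both tables hold selected genes.

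The control microglia libraries differed in the genes that co-culture raised most. Over the 30 genes raised more than 48-fold that had a co-culture mean of at least 50 FPKM, controls 1, 2 and 3 held a median of 1.70%, 0.85% and 1.12% of the co-culture mean, and control 1 was highest in 27. Control 1 exceeded control 2 by 0.83% (95% interval 0.73 to 0.91) of the co-culture mean in these genes and by 0.93% (0.57 to 1.02) in the 18 genes raised 16-fold to 48-fold with the same minimum, which may reflect a trace of co-culture material in control 1, though a few control cells in the same state would look alike. Against control 3 the shares were 0.53% (0.42 to 0.82) and 1.03% (0.61 to 1.4). These intervals overlap, but each median lay outside the other interval. The genes were sorted by fold, which uses the control mean, so the genes raised less held a larger control share. Differences between controls that scale with the control level would then also be larger in them. The intervals also treat genes as independent, which they are not. The comparison thus cannot decide on such a trace as the whole cause. No biological explanation was tested. Control 3 exceeded control 2 by 0.31% (0.14 to 0.44) in the former and by -0.27% (-0.70 to 0.35) in the latter, intervals that also overlap and the second of which spans 0, so such material in control 3 could not be decided.

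Of the 10 tested fibroblast and mural cell genes, 8 fell in co-cultured microglia, with log2 fold changes from -1.24 for Mgp to -3.71 for Acta2. The list did not pass the exact test of direction (adjusted p = 0.0694). Dcn and Serping1, 2 of the 10 members, rose, which a lower share of such cells as the whole cause would not give. With equal totals both lay above 0 and 1 was called. Which cells expressed them was not tested, and the rule was set after the values were seen, so a lower share was not excluded. All 10 were highest in co-culture 3, at a median of 1.85 times the mean of co-cultures 1 and 2 (range 1.54 to 2.14, against a median of 1.01 over the other called genes), which may reflect a larger share of such cells in that library. Il6 and Lcn2 had ratios of 2.12 and 2.13 there, and 157 other called genes reached 1.54. Whether the fall is a change within microglia, which the design names, stayed untested, and the labels name no sort of the cultured cells.

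Macrophage and neutrophil markers were higher in spinal cord Treg cells. RNA of microglia like the cultured ones could not supply the rise of Cd14, since C1qb, which would have needed 78.8 FPKM in the proportions of control microglia or 528 FPKM in those of co-cultured ones, had a mean of 1.21 FPKM and a highest value of 1.68 FPKM, in tables normalized separately. C1qb was itself among the genes the authors found changed, higher in the spinal cord, at a level below the filter. A smaller amount of such RNA was thus not excluded. Neutrophil RNA as the source of the largest rises stayed open. The highest S100a8 value of the spinal cord libraries was 3.29 times the lowest and that of Mmp8 2.02 times. The ratio was 1.11 for Ifitm3, 1.16 for Plac8, 1.70 for Slpi and 1.17 for Plaur. Ifitm3 and Slpi were highest in spinal cord library 1, where both markers were lowest. Plaur was highest in library 2 (305 FPKM), where both markers were highest, and Plac8 in library 3 (79.1 FPKM). The genes thus went different ways, and 2 marker genes, 3 libraries and the genes of the largest rises alone are too few to decide. Expression of these genes by Treg cells of the injured cord stayed open too, as untested, and so did RNA of macrophages unlike the cultured microglia.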
